A study of Mus musculus with 6 samples.

How the data were processed

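Expression was measured by sequencing of polyadenylated RNA in 6 libraries of mouse embryonic stem cell-derived motor neuron progenitors at day 4, 3 labelled control and 3 labelled Setd5sh. Per the labels' protocols, 500 cells were seeded per embryoid body on day 0, retinoic acid and SAG were given from day 2, the medium was changed on day 3, and RNA was extracted with TRIzol, selected on poly-T beads and primed with random hexamers. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

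The authors deposited a single table of 55400 genes with Ensembl identifiers, which holds a raw read count and an FPKM value per library and the exonic length of each gene. The submitters' processing notes name HISAT2, SAMtools, HTSeq, DESeq2 and the mm10 build, without roles or versions; the annotation release and whether counting used strand are not given in the sources used here. The deposited counts are whole numbers. The deposited FPKM values equal the count scaled by exonic length and by the column's total count in the usual way, to within 0.005 in each library, so no scaling between libraries beyond the total was applied to them. Symbols, positions and GC content came from GENCODE release M21 on the same build, in which 55140 identifiers, or 99.5%, were found.

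Before the data were examined, the design assumed that the table held FPKM only and set limma on log2(FPKM + 1) as the test. Since the table also holds counts, edgeR's quasi-likelihood test on the deposited counts was used as the main test, with the planned filter of a mean FPKM of at least 1 over the 6 libraries, which left 12199 genes, and the limma fit became an alternative. Libraries were scaled by TMM. Fold changes are Setd5sh minus control on the log2 scale with standard errors from edgeR, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was 0.05, two-sided. FPKM values in the text are the authors' deposited values. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and, for figures, matplotlib 3.10.9 were used.

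A set of 42 gene lists was fixed before the data were examined, and 40 had at least 3 tested members. The Hox genes of paralog groups 9 to 13, with 1 tested member, and the endothelial and blood genes, with 0, were not tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 40 lists, and again with a correlation estimated per list; fry was run beside it. The genes named in the text are Setd5; 10 markers fixed in advance from stem cell to motor neuron (Olig2, Nkx6-1, Pax6, Neurog2, Mnx1, Isl1, Lhx3, Sox2, Tubb3 and Pou5f1); since no gene passed, the 5 genes with the smallest p in each direction; and up to 4 members with the smallest p in each list described. In lists that did not pass, members were named only for postmitotic motor neuron and pluripotency genes, a choice made after the values were seen, and Chac1 and Insm1 were added in the same way. Single-gene results of 3 list members that the rule would name are not reported here.

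Both groups share the replicate numbers 1, 2 and 3. The deviations from the group means correlated across genes at 0.185, 0.69 and 0.127 for the same-numbered libraries, all above 0.1, so the numbers were taken to pair the samples, from the data and not from the labels. Control replicate 1 correlated slightly more with Setd5sh replicate 3, at 0.191, than with its own partner. In log2 level, control replicate 3 correlated more with Setd5sh replicate 2, at 0.9875, than with its own partner, at 0.983. Only the libraries numbered 2 clearly paired, so statements on pairs 1 and 3 rest on weak support. No 2 libraries agreed within sampling noise, with a chi-square of at least 8.5 per degree of freedom. The fits were also run with other scalings, filters, pseudocounts, variance models and tools, with the replicate number as a block, and without each library in turn. After the data were examined, fits with each library's smooth trend on GC content and exonic length removed, a fit without pair 1, and DESeq2 and limma with the replicate block were added. The fit without pair 1 has the replicate block, holds only the libraries numbered 2 and 3, and leaves 1 residual degree of freedom. Its single-gene calls are therefore weak support.

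The edgeR, DESeq2 and limma scripts were tested on simulated counts for the 12199 genes with 200 genes changed by known amounts. At the spread of the real data, edgeR recovered 94% of 4-fold and 41% of 2-fold changes with 14 false calls, and DESeq2 92% and 48% with 25, limma 87% and 23% with 7, and edgeR with the replicate block 90% and 21% with 2. A list raised in the simulation reached a camera adjusted p of 4.51e-09 with 0 false lists of 40. Simulated genes were independent, and no effect of the replicate number was simulated. The 0 false lists therefore do not measure false calls among lists of correlated genes.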

Results

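Polyadenylated RNA was sequenced from motor neuron progenitors that had been differentiated from C57BL/6 mouse embryonic stem cells and harvested on day 4. Retinoic acid at 1 µM, which gives neural cells a caudal identity, and SAG at 0.5 µM, a small molecule that activates Sonic hedgehog signalling and gives them a ventral identity, were present from day 2. The 6 libraries fall into 2 groups of 3, labelled control and Setd5sh. The form of the second name points to a short hairpin RNA against Setd5, but the labels do not spell it out. Doxycycline at 1 µg/mL for 36 h before harvest is described in the same words for both groups, so whether control cells carried another hairpin is not given in the sources used here. Total counts were 32046466, 27153918 and 19871993 in control replicates 1, 2 and 3, and 20726820, 27660851 and 19639303 in Setd5sh replicates 1, 2 and 3. The comparison addresses how gene expression in these progenitors differs when Setd5, a SET domain protein, is targeted.

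Setd5 mRNA was lower in each Setd5sh library than in each control library. In Setd5sh libraries as a group, integrated stress response genes such as Atf4, Atf5 and Sesn2 and young-neuron genes such as Tubb3 and Ina rose as lists, with median log2 fold changes of 0.79 and 0.38 (adjusted p = 0.214 with an estimated correlation for both). Against the control mean, the mean log2 level of the stress list was 1.01 and 0.93 in Setd5sh replicates 1 and 3. In Setd5sh replicate 2 it was -0.06, below control replicates 1 and 3. Hox genes of paralog groups 5 to 8 and dorsal neural tube genes also rose as lists (adjusted p = 0.214 with an estimated correlation for both), and hypoxia and glycolysis genes such as Bnip3 and Pdk1 fell as a list, with a median log2 fold change of -0.34 (adjusted p = 0.449 with an estimated correlation). The progenitor factors Olig2 and Sox2 stood at 73.6 and 74.6 FPKM in control and at 93.7 and 74.0 FPKM in Setd5sh. No single gene, Setd5 included, passed the adjusted threshold in the edgeR test over all genes, and no list passed with an estimated correlation between genes.

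Setd5 (ENSMUSG00000034269) lies on chromosome 6, from 113077365 to 113153435 on the plus strand of the mm10 build. Its level was 19.2 ± 2.76 FPKM in control libraries and 13.6 ± 0.755 FPKM in Setd5sh libraries (SD, n = 3 each), so that the Setd5sh mean was 70.6% of the control mean. Control replicates 1, 2 and 3 stood at 22.2, 18.8 and 16.7 FPKM, and the Setd5sh replicates at 14.4, 13.5 and 12.9 FPKM. Within pairs of the same replicate number, Setd5sh stood at 64.9%, 71.6% and 77.2% of control. The log2 fold change was -0.51 (SE 0.16), with an edgeR adjusted p = 0.995 and an unadjusted p of 0.0143 across 12199 genes. An exact two-sided permutation test on the 6 libraries gave p = 0.1, the smallest value that 3 against 3 allows. With GC and length trends removed and the replicate number as a block, an alternative chosen after seeing the data, the log2 fold change was -0.31.

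**Figure D1:**
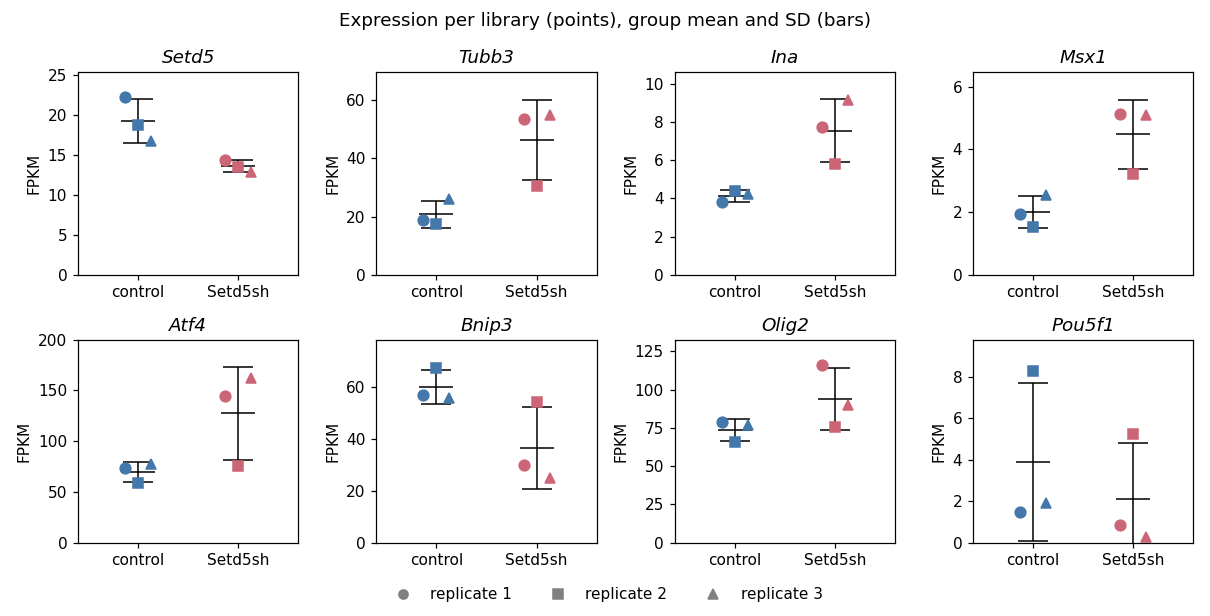
Expression in FPKM (vertical axes, from 0) of 8 genes in the 3 control and 3 Setd5sh libraries; points are libraries, marker shapes are replicate numbers, and bars are the group mean and SD. Setd5 was lower in each Setd5sh library than in each control library, Tubb3, Ina and Msx1 were higher in each, and the 2 libraries numbered 2 held the highest Pou5f1 values, 8.31 and 5.23 FPKM; the lower SD bars of Pou5f1 are limited at 0.

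Integrated stress response genes, a list fixed from general knowledge that includes Atf4 itself, rose as a list. Only mRNA was measured, not the activity of the pathway. Of 24 tested members, 21 had a positive log2 fold change and 11 had an unadjusted p under 0.05, all of them higher. The camera adjusted p was 2.38e-23, against adjusted p = 0.214 with an estimated correlation. None of the 24 passed in edgeR adjusted over all genes or adjusted over the list alone. Sesn2, Atf5, Pck2, Atf4 and Chac1 each passed over all genes with no filter and in the fit with the replicate block without pair 1, an alternative chosen after seeing the data. That fit without pair 1 leaves 1 residual degree of freedom. Atf5 stood at 54.8 ± 20.7 FPKM in Setd5sh and 27.6 ± 3.64 FPKM in control, a log2 fold change of 0.98 (SE 0.31). Atf4, the transcription factor that the pathway acts through, had a log2 fold change of 0.86 (SE 0.29), Sesn2 one of 1.05 (SE 0.33), and Pck2, the mitochondrial form of phosphoenolpyruvate carboxykinase, one of 0.95 (SE 0.31). These 4 genes were higher in Setd5sh in all 3 pairs. The difference between paired libraries in the mean log2 level of the list was 0.77, 0.22 and 0.90 for pairs 1, 2 and 3. Chac1, an enzyme that degrades glutathione, is a member chosen for mention after its values were seen, and had 25.8 ± 15.96 FPKM in Setd5sh against 9.15 ± 4.15 FPKM in control. DESeq2 with the replicate number as a block, an added alternative, gave Chac1 a log2 fold change of 1.33 (SE 0.27) with an adjusted p of 0.00409, against 0.938 and 0.937 with the same block in edgeR and limma.

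Pan-neuronal genes rose as a list as well, with 18 of 19 tested members at a positive log2 fold change. The camera adjusted p was 1.94e-15, against adjusted p = 0.214 with an estimated correlation. None passed in edgeR over all genes, apart from Tubb3 in some alternatives, and 5 passed adjusted over the list alone, namely Tubb3, Ina, Neurog1, Insm1 and Cntn2, of which Insm1 was chosen for mention after its values were seen. That adjustment was made within each list and not across the 40 lists. Only this list and the dorsal neural tube list had such members. Tubb3 (ENSMUSG00000062380, chromosome 8, from 123411424 to 123422015 on the plus strand), which encodes the neuronal beta-tubulin, stood at 46.4 ± 13.7 FPKM in Setd5sh and 20.8 ± 4.68 FPKM in control (SD, n = 3 each). Its log2 fold change was 1.15 (SE 0.27), with an edgeR adjusted p of 0.995, and DESeq2 with the replicate block gave 1.13 (SE 0.23) with an adjusted p of 0.00409, against 0.938 and 0.937 with the block in edgeR and limma. edgeR called Tubb3 with no filter, and with the block without pair 1 at an adjusted p of 2.4e-05. The latter fit holds only the libraries numbered 2 and 3 and leaves 1 residual degree of freedom. Ina, a neuronal intermediate filament gene, had a log2 fold change of 0.86 (SE 0.21), the adhesion gene Cntn2 one of 0.91 (SE 0.24), the proneural gene Neurog1 one of 0.70 (SE 0.19) and Insm1 one of 0.48 (SE 0.15), and all 5 were higher in all 3 pairs. The list median ranged from 0.27 without control replicate 3 to 0.72 without control replicate 1, and was 0.64 without Setd5sh replicate 2.

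The factors that mark motor neuron progenitors rose slightly as a list, with a median log2 fold change of 0.22 and 6 of 9 tested members positive. The camera adjusted p was 0.001, against adjusted p = 0.249 with an estimated correlation; the median was 0.35 without control replicate 3 and 0.14 without Setd5sh replicate 1. None of the 9 passed in edgeR over all genes or adjusted over the list alone. A range beside an SE, here and below, is that of the log2 fold change without single libraries, given where it moved by over 1.5 times. Olig2 stood at 93.7 ± 20.4 FPKM in Setd5sh and 73.6 ± 7.04 FPKM in control, a log2 fold change of 0.34 (SE 0.20, range 0.14 to 0.51). Neurog2 had a log2 fold change of 0.64 (SE 0.19), Olig1 one of 0.55 (SE 0.21) and Nkx6-1 one of 0.38 (SE 0.21, range 0.24 to 0.57), and these 4 were higher in Setd5sh in all 3 pairs. Pax6 and Sox2 had log2 fold changes of -0.01 (SE 0.19) and -0.02 (SE 0.14), and the sign of both turned under some settings. Genes switched on as motor neurons leave the cell cycle did not pass as a list, with a median of -0.03 over 9 members and a camera adjusted p of 0.823. Mnx1 stood at 9.77 ± 6.44 FPKM in Setd5sh and 14.9 ± 6.81 FPKM in control, a log2 fold change of -0.61 (SE 0.47, range -1.25 to -0.21). It was lower in all 3 pairs, with an unadjusted p of 0.0145 with the replicate block. It passed in edgeR with the block without pair 1, at an adjusted p of 0.0185. Isl1 had a log2 fold change of 0.53 (SE 0.53, range 0.17 to 1.21), and the receptor genes Gfra1 and Ret had -0.54 (SE 0.25, range -0.65 to -0.33) and 0.26 (SE 0.21, range 0.13 to 0.43). Lhx3 was under the expression minimum, at 0.597 FPKM in control and 0.63 FPKM in Setd5sh.

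Patterning genes moved in several lists. Hox genes of paralog groups 5 to 8, which belong to cervical and brachial levels, had a median log2 fold change of 0.41, and 7 of 8 tested members were positive. The camera adjusted p was 2.55e-08, against adjusted p = 0.214 with an estimated correlation, and the median was 0.69 without control replicate 3. Hoxb6 had a log2 fold change of 0.65 (SE 0.19), Hoxb8 one of 0.64 (SE 0.22), Hoxa7 one of 0.72 (SE 0.32) and Hoxb5 one of 0.49 (SE 0.23, range 0.32 to 0.75). The hindbrain Hox genes of paralog groups 1 to 4 had a median of 0.17, with 11 of 12 positive and a camera adjusted p of 0.00786, against adjusted p = 0.214 with an estimated correlation. Hoxb2 had a log2 fold change of 0.28 (SE 0.14), Hoxa4 one of 0.37 (SE 0.26, range 0.17 to 0.67), Hoxa3 one of 0.23 (SE 0.18, range 0.096 to 0.35) and Hoxd3 one of -0.52 (SE 0.43), which turned to 0.19 without control replicate 1. Without control replicate 2 that list was at a camera adjusted p of 0.0625, and without Setd5sh replicate 3 its median was 0.10. Dorsal neural tube genes had a median of 0.61, but only 4 of the 23 fixed members were expressed enough to be tested. The camera adjusted p was 3.28e-05, against adjusted p = 0.214 with an estimated correlation, and Msx1 and Wnt1 passed adjusted over the list alone. That adjustment covered only the 4 tested members and was not made across lists. Msx1 stood at 4.48 ± 1.10 FPKM in Setd5sh and 2.01 ± 0.517 FPKM in control, a log2 fold change of 1.15 (SE 0.30). It passed over all genes with no filter and, at an adjusted p of 0.0131, with the replicate block without pair 1. Wnt1 had a log2 fold change of 0.84 (SE 0.27) and Zic2 one of -0.22 (SE 0.31), which turned to 0.01 without control replicate 2.

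Signalling lists rose by smaller amounts. Notch pathway genes had a median log2 fold change of 0.12 over 21 members (camera adjusted p of 0.000211, against adjusted p = 0.365 with an estimated correlation). Dll3 had a log2 fold change of 0.68 (SE 0.24), Nrarp one of 0.55 (SE 0.22), Hes5 one of 0.53 (SE 0.25, range 0.24 to 0.71) and Maml1 one of 0.24 (SE 0.15). The Notch median was 0.21 without control replicate 1, 0.24 without control replicate 3, 0.23 without Setd5sh replicate 2 and 0.21 without Setd5sh replicate 3. FGF and ERK feedback genes had a median of 0.12 over 13 members (camera adjusted p of 0.000211, against adjusted p = 0.214 with an estimated correlation), and this median was 0.21 without control replicate 2, 0.18 without control replicate 3 and 0.17 without Setd5sh replicate 1. Fgf15 had a log2 fold change of 0.70 (SE 0.23), Etv5 one of 0.72 (SE 0.30), Dusp6 one of 0.51 (SE 0.23, range 0.33 to 0.65) and Spred2 one of 0.24 (SE 0.15). Wnt pathway genes had a median of 0.07 over 20 members (camera adjusted p of 0.00154, against adjusted p = 0.214 with an estimated correlation), with Sp5 at 0.80 (SE 0.23), Sfrp2 at 0.62 (SE 0.23), Myc at 0.72 (SE 0.27) and Ccnd1 at 0.52 (SE 0.22, range 0.28 to 0.68). The Wnt list lost its call without control replicate 1, at a median of 0.13 and a camera adjusted p of 0.0998, and its median was 0.17 without control replicate 3, 0.05 without Setd5sh replicate 1 and 0.11 without Setd5sh replicate 2. Sonic hedgehog pathway genes had a median of 0.13 over 16 members (camera adjusted p of 0.0178, against adjusted p = 0.214 with an estimated correlation), with Sufu at 0.34 (SE 0.17, range 0.22 to 0.45), Gli2 at 0.19 (SE 0.14), Cdon at -0.19 (SE 0.16, range -0.28 to -0.10) and Nkx2-2 at 0.38 (SE 0.34, range 0.16 to 0.66), and stood at a camera adjusted p of 0.0776 without control replicate 2.

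BMP and TGF-beta response genes had a median log2 fold change of 0.07 over 14 members (camera adjusted p of 0.0343, against adjusted p = 0.423 with an estimated correlation), and the 4 with the smallest p went both ways: Msx1 and Ltbp1, at 0.34 (SE 0.17, range 0.23 to 0.49), were higher, and Skil, at -0.56 (SE 0.30, range -0.83 to -0.18), and Tgfbi, at -0.64 (SE 0.38, range -0.85 to -0.36), lower. This list had a camera adjusted p of 0.755 without control replicate 1, with a median of -0.03, 0.0939 without Setd5sh replicate 2, with a median of 0.10, and 0.0852 without Setd5sh replicate 3, with a median of 0.12. The median was 0.14 without control replicate 2, 0.22 without control replicate 3 and 0.18 without Setd5sh replicate 1. Axon guidance genes had a median of 0.08 over 25 members (camera adjusted p of 0.0364, against adjusted p = 0.295 with an estimated correlation), with 15 positive and a mean of 0.019. Beside Cntn2 they include Slit3 at 0.52 (SE 0.23), Plxna2 at -0.25 (SE 0.15, range -0.33 to -0.15) and Ephb2 at 0.22 (SE 0.14, range 0.14 to 0.33). The axon guidance call was lost without control replicate 2, control replicate 3, Setd5sh replicate 1 or Setd5sh replicate 3, at camera adjusted p of 0.152, 0.369, 0.108 and 0.163, with a median of 0 without Setd5sh replicate 3. Its median was 0.13 without control replicate 1 and 0.14 without Setd5sh replicate 2. With GC and length trends removed and the replicate number as a block, 6 of the called lists no longer passed: Hox 1 to 4, Wnt, Sonic hedgehog, BMP and TGF-beta, axon guidance and mitochondrially encoded genes, at camera adjusted p of 0.0693, 0.0982, 0.179, 0.13, 0.113 and 0.517. Their medians (with the SD over members) went from 0.17 (0.23) to 0.16 (0.20), 0.073 (0.38) to 0.036 (0.38), 0.13 (0.16) to 0.076 (0.14), 0.067 (0.43) to 0.086 (0.40), 0.077 (0.37) to 0.064 (0.26) and -0.53 (0.46) to 0.11 (0.30). The median of all genes, against which camera sets a list, went from -0.043 to 0.013. The medians of Hox 1 to 4, BMP and TGF-beta and axon guidance genes changed little in themselves, but their distance from the median of all genes shrank. The Wnt and Sonic hedgehog medians shrank and the mitochondrial one turned. GC content or length stays a candidate cause for all 6 lists, and a lost call alone does not show that it made the shift. With the offsets alone all 6 lists that lost their call and 2 more did not pass, motor neuron progenitor factors at 0.116 and Notch genes at 0.0647.

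Metabolic and growth genes moved both ways. Hypoxia and glycolysis genes fell as a list, with 25 of 27 tested members below 0 and a median log2 fold change of -0.34. The camera adjusted p was 8.69e-08, against adjusted p = 0.449 with an estimated correlation. Bnip3, a mitophagy receptor induced by low oxygen, stood at 36.4 ± 15.8 FPKM in Setd5sh and 60.0 ± 6.50 FPKM in control, a log2 fold change of -0.73 (SE 0.28, range -1.10 to -0.52). Pdk1 had a log2 fold change of -0.60 (SE 0.24), Pfkp one of -1.26 (SE 0.55, range -2.02 to -0.90) and P4ha1 one of -0.59 (SE 0.27, range -0.91 to -0.36), and these 4 were lower in all 3 pairs. None of the 27 passed in edgeR over all genes or adjusted over the list alone. Bnip3, Pfkp and P4ha1 passed with the replicate block without pair 1, at adjusted p of 0.00144, 0.000667 and 0.0372, and Pfkp also with no filter. The difference between paired libraries in the mean log2 level of the list was -0.25, -0.16 and -0.87. For pluripotency genes it was -0.30, -0.35 and -0.95. Both lists put the 6 libraries in the same order, from control replicate 2 down to Setd5sh replicate 3. The hypoxia median was -0.20 without Setd5sh replicate 3, at a camera adjusted p of 0.0489, and -0.21 without control replicate 2. Ribosome biogenesis and MYC target genes rose as a list, with a median of 0.14 over 28 members (camera adjusted p of 0.000163, against adjusted p = 0.423 with an estimated correlation), including Myc, the spermidine synthase gene Srm at 0.51 (SE 0.20), Nop2 at 0.42 (SE 0.18) and Rrp12 at 0.33 (SE 0.17, range 0.21 to 0.45). This call was lost without control replicate 2, at a camera adjusted p of 0.116 and a median of 0.09, and the median was 0.08 without Setd5sh replicate 1, 0.23 without control replicate 1 and 0.24 without Setd5sh replicate 2. Cholesterol synthesis genes had a median of 0.09 over 25 members (camera adjusted p of 0.0204, against adjusted p = 0.584 with an estimated correlation), with Mvk at 0.31 (SE 0.18) and Stard4 at -0.45 (SE 0.31), which turned to 0.009 without control replicate 1. The list had a camera adjusted p of 0.565 without control replicate 2, with a median of 0.01, 0.0846 without control replicate 3, with a median of 0.14, and 0.436 without Setd5sh replicate 1, with a median of 0.04. Without control replicate 1 the cholesterol median was 0.18.

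Control replicate 1 stood apart from the other 5 libraries. It held 2.18% of its counts in mitochondrially encoded genes, against 0.718% to 1.41% in the others, and 4.79% in genes under 40% GC, against 1.72% to 2.67%. The nuclear RNA Malat1 stood at 213 FPKM there and at 22.2 to 41.0 FPKM elsewhere. Mitochondrially encoded genes, which had a median log2 fold change of -0.53 over 13 members (camera adjusted p of 0.0204, against adjusted p = 0.626 with an estimated correlation), turned to 0.29 without that library, at a camera adjusted p of 0.0117. Among them, mt-Nd4l had a log2 fold change of -1.85 (SE 0.98), on 123 counts in control replicate 1 and only 5 to 15 in each other library. The log2 fold change was -0.68 (SE 0.47) for mt-Co3, -0.93 (SE 0.69) for mt-Nd6 and -0.66 (SE 0.60) for mt-Atp6. Without control replicate 1, mt-Nd4l, mt-Co3, mt-Nd6 and mt-Atp6 became 0.17, -0.085, 0.53 and 0.031. The call was lost without Setd5sh replicate 2, at a median of -0.26 and a camera adjusted p of 0.648, and the median was -0.86 without control replicate 2 and -0.94 without Setd5sh replicate 3. Neuroepithelial progenitor genes had a median of -0.01 over 22 members while their test and mean pointed the other way (camera adjusted p of 0.0204, against adjusted p = 0.626 with an estimated correlation), with Ednrb at -0.70 (SE 0.29, range -0.88 to -0.25), Vim at 0.45 (SE 0.19) and Sox21 at 0.39 (SE 0.17), beside Hes5. Their median was 0.36 without control replicate 1, 0.13 without Setd5sh replicate 2 and 0.06 without Setd5sh replicate 3. Their camera adjusted p was 0.672, 0.369 and 0.403 without control replicate 2, control replicate 3 or Setd5sh replicate 1, with medians of -0.08, 0.03 and -0.08. Without control replicate 1, edgeR still called 0 genes, with 361 at an unadjusted p under 0.05. It called 22 lists, 15 of them among the 17, and these 15 include the mitochondrially encoded genes in the opposite direction.

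**Figure D2:**
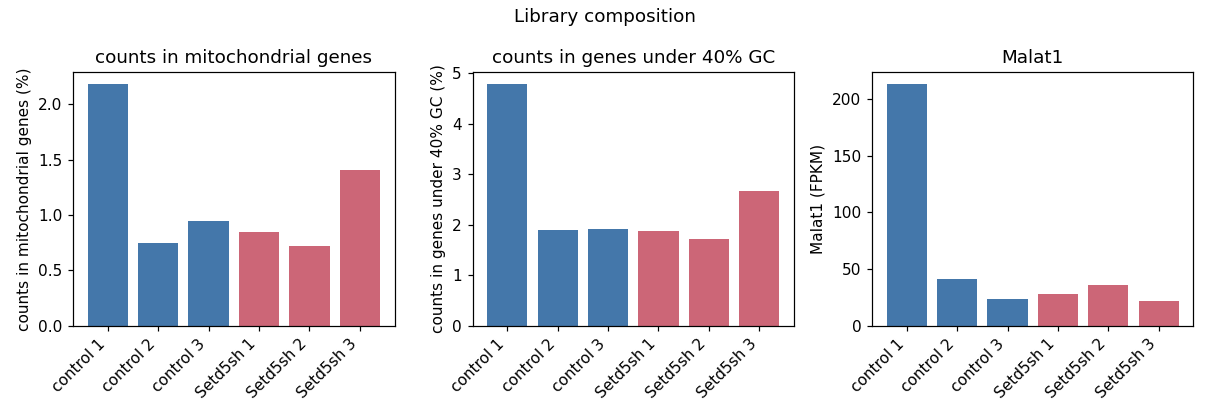
Share of counts in mitochondrially encoded genes (%), share of counts in genes under 40% GC (%) and Malat1 level (FPKM) in each of the 6 libraries, with bars starting at 0. Control replicate 1 is the highest of the 6 in each panel, at 2.18%, 4.79% and 213 FPKM.

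Genes of other cell types that the cultures could hold gave few calls. Pluripotency genes had 8 tested members, all below 0, with a median of -0.41 and a camera adjusted p of 0.0518, which became 0.000511 with the replicate number as a block, against adjusted p = 0.626 and 0.423 with an estimated correlation. Without control replicate 1 this list was at a median of -0.71 and a camera adjusted p of 0.000273, without Setd5sh replicate 2 at -1.11 and 4.76e-06, and without control replicate 2 at 0.13 and 0.672. Pou5f1 stood at 2.12 ± 2.71 FPKM in Setd5sh and 3.91 ± 3.82 FPKM in control, a log2 fold change of -0.86 (SE 1.01), with a call in edgeR with the block without pair 1 (adjusted p of 0.00239), and Dppa4, Zfp42 and Klf5 had log2 fold changes of -0.65 (SE 0.50), -0.69 (SE 0.73) and -0.36 (SE 0.29). Without single libraries they ranged from -2.73 to 0.28, -1.40 to -0.32, -2.02 to -0.21 and -0.52 to -0.15. These 4 genes were lower in Setd5sh in all 3 pairs. Floor plate and p3 genes (median 0.19), V0 to V2 domain genes (0.07), neural crest genes (0.06), glial genes (-0.06), fibroblast genes (-0.00) and mesoderm and endoderm genes (-0.04) did not pass, at camera adjusted p of 0.207, 0.246, 0.0934, 0.264, 0.207 and 0.652. For the glial, fibroblast and mesoderm and endoderm lists the median and the test differed in sign. S phase genes had a median of 0.06 and a camera adjusted p of 0.0518, and immediate early and heat shock genes a median of 0.12 and a camera adjusted p of 0.0702; both became 0.0448 with the replicate block, against adjusted p = 0.423 and 0.661 with an estimated correlation and the block. The 13 other tested lists, among them those of Setd5 partner complexes, SET domain methyltransferases, Polycomb, p53 and interferon, had camera adjusted p from 0.0982 to 0.953.

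**Figure D3:**
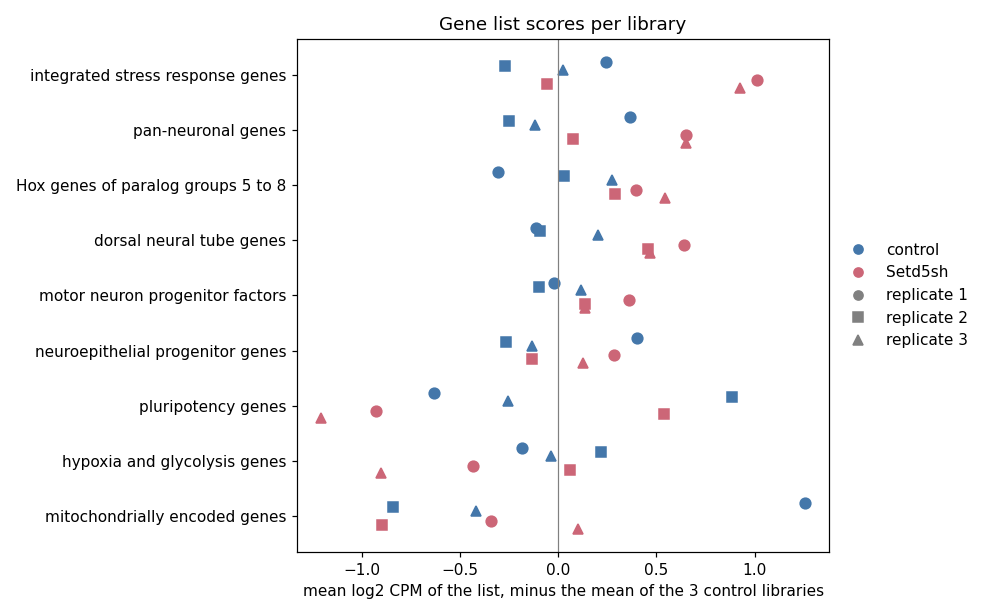
Mean log2 CPM of 9 gene lists in each library, minus the mean of the 3 control libraries (horizontal axis); each row is a list, colours are groups and marker shapes are replicate numbers. Setd5sh replicates 1 and 3 lie at 1.01 and 0.93 for integrated stress response genes and Setd5sh replicate 2 at -0.06, and both libraries numbered 2 lie highest for pluripotency genes, at 0.88 and 0.54.

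Across all genes, edgeR's quasi-likelihood test called 0 of 12199 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 149 genes, 75 higher and 74 lower, where 6 exchangeable libraries would give 610. DESeq2 and limma on log2(FPKM + 1) also called 0 genes each, with 221 and 152 at an unadjusted p under 0.05, and edgeR with the replicate block called 0, with 328. Other edgeR fits passed 610, with 910 genes under GC and length offsets with the replicate block and 662 without pair 1 with that block. Without single libraries the number ranged from 26 without Setd5sh replicate 1 to 963 without control replicate 3. The 3 libraries of one group lay entirely above or below the other 3 for 646 genes, or 5.30%, against the 10% of 6 exchangeable libraries. Libraries that resemble each other in pairs, as those numbered 2 do, lower both of these reference values. The 5 genes with the smallest p among those higher in Setd5sh, none of which passed, were Cyp26b1, a retinoic acid degrading enzyme, at a log2 fold change of 0.64 (SE 0.15; adjusted p of 0.0346 with the block without pair 1), Tubb3, Ina, Msx1 and the axon guidance gene Draxin at 0.80 (SE 0.21). Among those lower, none of which passed, they were Dab2 at -0.78 (SE 0.24), Spag16 at -0.96 (SE 0.30), Itih5 at -0.81 (SE 0.26), Setd5, and Retreg1 at -0.65 (SE 0.22). In all, 17 of 40 lists passed with camera's preset correlation, 15 higher and 2 lower, and 0 passed with an estimated correlation or in the fry test, whose smallest adjusted p were 0.214 and 0.369. On simulated counts with the spread of these libraries, edgeR recovered 94% of genes changed 4-fold and 41% of genes changed 2-fold. The simulation held independent genes, without effects of the replicate number or GC trends, so these shares are only a guide to the real libraries. For 2-fold changes the figure was 21% with the replicate block, 23% in limma and 48% in DESeq2, so in each a simulated gene changed 2-fold was missed more often than called. With no effect of the replicate number simulated, the 21% does not describe the block in libraries that pair.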

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

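The fits with GC and length offsets, without pair 1, and DESeq2 and limma with the replicate block were chosen after seeing the data. The fit without pair 1 leaves 1 residual degree of freedom, so its calls are weak support. The Setd5 log2 fold change was negative in all 24 refits, from -0.61 to -0.31, and passed in none (smallest edgeR adjusted p 0.324, without pair 1 with the replicate block). The number of genes called, 0 at first, became 73 with edgeR and no filter (18 higher, 55 lower), of which 59 were among the 12199 genes tested at first, 70 with edgeR without pair 1 and with the replicate block (30 higher, 40 lower), of which 21 were shared with the unfiltered calls, and 2 with DESeq2 and the replicate block (2 higher, 0 lower); the cause was not tested. The 1.5-fold size threshold gave 0 by necessity, since it was set on the called genes, and leaving out any single library gave 0 in edgeR. The number of lists called, 17 at first, was 26 with no filter, 11 with GC and length offsets and 0 with an estimated correlation, and 15 to 22 without single libraries. It was 20 with the replicate block, which kept all 17, added pluripotency, S phase and immediate early genes, and changed no other call, edgeR genes included, where it gave 0. With both the GC and length offsets and the replicate block 13 lists passed, 11 of them among the 17, and without pair 1 19 passed, 13 of them among the 17. Lists shared with the 17 were counted whatever their direction.

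Genes and lists to which the text gives a value were compared over all alternatives. Of 1875 gene values, 1818 kept their direction and side of the threshold, 23 became significant and 34 turned. Since no gene passed at first, keeping its side only meant staying uncalled, and no gene call could be lost. Of 670 list values, 542 kept direction and side, 73 lost and 38 gained the call, and 17 turned. This set was narrowed after the wider one had been computed, which held every list and 4 members of each: there, 89 of 3819 gene values and 61 of 994 list values turned. Leaving out 1 library changed the log2 fold change of 38 of 79 named genes besides Setd5 by more than 1.5 times or turned it. The integrated stress response, pan-neuronal, Hox 5 to 8, hypoxia, dorsal and FGF lists kept their call in all refits that tested them with the preset correlation, and 8 of the 17 in all 6 that left out 1 library.

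Pax6, near 0 at first, turned to 0.004 with median-ratio or total-count scaling or DESeq2, 0.003 with the replicate block, 0.069 with no filter, 0.01 with the limma fits on FPKM + 1 (also without trend, robust or with the replicate block), 0.012 on FPKM + 0.1, 0.013 on TPM, 0.052 with quantile normalization, 0.078 with GC and length offsets, 0.075 with the replicate block added, 0.19 without pair 1, and 0.015 with DESeq2 and the replicate block; without single libraries it ranged from -0.12 to 0.18. Sox2 turned to 0.044 with no filter and ranged from -0.053 to 0.044 without single libraries, Pou5f1 from -2.73 to 0.28, Zic2 from -0.54 to 0.013 and mt-Nd4l from -2.33 to 0.17; mt-Nd4l was 0.051 without pair 1. Hoxd3 ranged from -0.795 to 0.186, Stard4 from -0.669 to 0.009, mt-Nd6 from -1.356 to 0.533 and mt-Atp6 from -1.24 to 0.031, each turning without control replicate 1. mt-Nd6 also turned to 0.099 with GC and length offsets, 0.147 with the replicate block added and 0.369 without pair 1, and mt-Atp6 to 0.227 without pair 1. The test of the postmitotic motor neuron list turned, at a median of 0.13 with no filter and 0.088 with quantile normalization, and its median ranged from -0.15 to 0.22 without single libraries. The same ranges were -1.11 to 0.13 for pluripotency, -0.21 to 0.080 for mesoderm and endoderm, -0.11 to 0.073 for fibroblast, -0.027 to 0.20 for immediate early and -0.94 to 0.29 for mitochondrially encoded genes. The mesoderm and endoderm test turned at medians of -0.071 with GC and length offsets, -0.051 with the replicate block added, -0.18 without pair 1 and 0.044 with DESeq2 and the replicate block, and the fibroblast test at -0.058 without pair 1. Mitochondrially encoded genes turned to 0.04 with GC and length offsets, 0.11 with the replicate block added and 0.32 without pair 1. Apart from fewer libraries where some were left out, the cause was not tested. In simulations, the spread between libraries limited single-gene calls more than the depth of 19639303 to 32046466 counts did. At this depth the 4 fits recovered 21% to 48% of 2-fold changes at the real spread and 95% to 97% at a low one, with no effect of the replicate number simulated.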

Other observations

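The tests of GC content and length, of single libraries and dishes, of stem cell share and motor neuron path, and of nuclear RNA were chosen after the results were seen; those of mitosis and of other splits were written before.

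The libraries numbered 2 in both groups held the most pluripotency transcripts. Pou5f1 stood at 8.31 FPKM in control replicate 2 and 5.23 FPKM in Setd5sh replicate 2, against 0.27 to 1.93 FPKM in the other 4 libraries, and Zfp42 at 2.39 and 2.02 FPKM, against 0.31 to 1.28 FPKM. Mnx1 was also highest in these 2 libraries, at 22.8 and 17.1 FPKM, against 5.05 to 11.3 FPKM elsewhere. Atf4 was lowest among Setd5sh libraries in replicate 2, at 75.8 FPKM, against 144 and 162 FPKM in replicates 1 and 3, and Chac1 stood at 7.49 FPKM there, against 36.8 and 33.2 FPKM.

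Integrated stress response genes were higher as a list (adjusted p = 0.214 with an estimated correlation), with Setd5sh replicates 1 and 3 at 1.01 and 0.93 but Setd5sh replicate 2 at -0.06, below control replicates 1 and 3 at 0.24 and 0.03. With each library's trend on GC content and length removed and the replicate block, their median log2 fold change was 0.69, which argues against that trend as the whole cause. The lowest median without any single library was 0.59, which argues against one library alone. Culture differences between single dishes stay open and cannot be told apart from the groups. The smallest difference within a pair was 0.22, below the range of 0.51 between the control libraries, a range that also holds any spread between replicate numbers. A lower share of undifferentiated stem cells was not tested for this list and stays open too. Control replicate 2 and Setd5sh replicate 2 had the highest pluripotency scores, 0.88 and 0.54, and the lowest stress response scores, -0.27 and -0.06. An effect of the Setd5sh construct is the biological explanation the design names, and it stays untested beside these.

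Pan-neuronal genes were higher as a list (adjusted p = 0.214 with an estimated correlation), and with the GC and length trends removed and the replicate block their median was 0.51, which argues against those trends as the whole cause. In the same fit their median exceeded that of postmitotic motor neuron genes by 0.57 (permutation p = 0.00034 over 19 and 9 genes, which are not independent replicates). This cannot exclude a general advance along the motor neuron path, since only 9 of 20 fixed postmitotic members were expressed enough to be tested. On that path, Neurog2 and Isl1 were at 0.56 and 0.65 in that fit and Mnx1 at -0.80. The pan-neuronal median exceeded that of neuroepithelial genes by 0.34 (permutation p = 3e-05), whose median was 0.17 there and 0.36 without control replicate 1. It exceeded that of Hox 1 to 4 genes, a comparison added last with both medians already seen, by 0.35 (permutation p = 0.00324). All these comparisons were chosen after the pan-neuronal rise had been seen, so their small permutation p are no independent support. A lower share of undifferentiated stem cells still cannot be told apart, since pluripotency genes were lower in that fit, at a median of -0.37 (camera adjusted p of 0.000185). Differences between dishes and an effect of the Setd5sh construct stay open and untested here.

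Control replicate 1 differed from the rest in composition. Removing each library's trend on GC content and length took away 55.3% of its mean squared deviation from the other libraries, against 6.40% to 30.4% for the others, so a GC or length bias is a candidate cause of most of it. After that, 4 nuclear RNAs other than Malat1, which prompted the test, kept a median excess of 0.59 (log2), above 99.1% of 10000 random sets, which is consistent with more nuclear RNA, although Rian was at -1.30, Meg3, Rian and Mirg share one locus, and mitochondrial transcripts were also raised in this library. The G2 and M phase genes kept 0.11 of an excess of 0.38, a value between the bounds set in advance, so more cells in mitosis cannot be told apart from the trend. Apart from mitosis, no biological explanation was tested.

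With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. edgeR called 0 genes in the real split, so all 10 gave as many by necessity and this count decides nothing. At an unadjusted p under 0.05 the real split gave 149 genes and another gave 2429, a split that sets control replicate 1 with Setd5sh replicates 1 and 3 against the rest and points to a structure of the samples other than the groups. The real split gave 17 lists and the highest of the others 18, from that same split, so 2 of the 10 gave as many. Among the 4 splits that part all 3 pairs, with the replicate block, the real one gave 20 lists and the highest of the others 9, so 1 of the 4 gave as many, again too few for a share under 0.05. By genes at an unadjusted p under 0.05 in those 4, the real split gave 328 and the highest of the others 1441, from the split that exchanges the labels of pair 3, so 2 of the 4 gave as many.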
